A study of Homo sapiens with 12 samples.

How the data were processed

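RNA sequencing of HepG2 cells in 4 groups of 3 biological replicates was used: HDAC1 wild type and HDAC1_S434A, each without and with H89. The deposited values are whole counts of read pairs per gene, made by the authors with featureCounts 2.0.1 over exons (options -p, -t exon and -g gene_id), per the file headers. The header names an hg19 annotation and sets no option for strand, multimapping or overlapping features. Alignment with Bowtie 0.12.2 to hg19 is stated per the submitters' processing notes. Read trimming, library kit, strandedness and sequencing batches are not given in the sources used here. The series design states thresholds of a fold change over 2 and an adjusted p-value under 0.05, which were used for all calls.

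The counts were taken as deposited and 62475 gene identifiers were read, of which 39746 were matched to a gene symbol by the unversioned identifier. Positions, gene lengths and identifiers are those of the deposited table (hg19). Gene types and GC content came from GENCODE annotation of another build through the identifiers, and 14280 of the 14435 genes tested had a GC value. Total counts per library ran from 17562754 to 37187794, and each gene's precision is given by the spread between replicates.

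The tests, the lists of genes, the rule for named genes and the alternatives without a note below were chosen before the data were examined. All 12 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3) with TMM factors, the filter filterByExpr by group (minimum count 10) and robust quasi-likelihood F tests without a block. The 5 comparisons were S434A vs WT without H89, H89 effect in WT, H89 effect in S434A, S434A vs WT with H89 and the difference of H89 effects between genotypes. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled.

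A total of 28 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. A test of each list against no change used fry from the same package. In counts of list members, "rose" and "fell" mean an adjusted p under 0.05 at any fold. The lists were cAMP/PKA/CREB-responsive genes, gluconeogenesis and glycogen, glycolysis, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPARA targets, hepatocyte secreted proteins, acute phase and complement, hepatocyte transcription factors, bile acid and xenobiotic metabolism, cell cycle, p53 targets and cell cycle arrest, the HDAC family, class I HDAC corepressor complexes, PKA subunits and cAMP signalling, SRF and YAP targets, unfolded protein and integrated stress response, hypoxia, interferon, NF-kB and inflammatory genes, NRF2 and metallothioneins, epithelial and mesenchymal genes, and autophagy and lysosome. Markers of fibroblasts and of blood and endothelial cells, and mitochondrially encoded, replication-dependent histone and heat shock genes as signs of cell identity and RNA quality, completed them.

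Named genes followed a fixed rule. HDAC1 was named in every library. For each comparison of 2 groups, the 10 largest rises and the 10 largest falls were named among called genes with a plain symbol, a mean of at least 2 CPM in the higher group and no overlap between the libraries of the groups (chance gives such a separation for 10% of genes with 3 against 3). Up to 4 members with the smallest p were named of each list described, or up to 2 with the highest mean as values where none passed. For the difference of H89 effects the 5 smallest p-values in each direction were named. A few genes that the rule names are not reported here.

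Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter other than a nonzero total, at least 1 CPM in at least 3 libraries, only the groups compared, the replicate number as a block, and leaving out each replicate in turn. Alternatives added after seeing the data were the removal of each library's smooth trend on GC content and gene length by an offset (splines with 5 degrees of freedom on each, with their product), the same without replicate 1 of S434A without H89, and limma-voom with a quality weight per group. For comparisons that share controls, unchanged groups were simulated in 20 draws.

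The steps were tested on simulated data with the means, library sizes and spreads of the real groups, with 200 changed genes and 1 list raised by 1.5-fold. Genes were drawn independently and without GC or length trends. Of 50 genes changed by 3-fold, the share called was 90% for S434A vs WT without H89 (14249 genes), 94% for H89 effect in WT (14266 genes), 90% for H89 effect in S434A (14249 genes), 94% for S434A vs WT with H89 (14245 genes) and 62% for the difference of H89 effects (14249 genes). Unchanged genes called numbered 89, 0, 85, 0 and 28 in the same order, and 330, 0, 336, 0 and 45 passed the adjusted p at any fold. Limma-voom with a weight per group called 55, 5, 45, 0 and 57 unchanged genes. The raised list was recovered in all 5 comparisons, and 1 other list was called in each of the first 4. Python 3.11.15 and matplotlib 3.10.9 drew the figures.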

Results

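Messenger RNA was measured by RNA sequencing in 12 libraries of HepG2 cells, a human liver cancer line. The cells carried wild-type HDAC1 (WT) or the HDAC1_S434A mutant (S434A), each without or with H89, an inhibitor of protein kinase A (PKA), in 3 biological replicates per group. HDAC1 is a class I histone deacetylase, and the mutation replaces a serine by alanine. The dose and duration of H89 and the way the mutant cells were made are not given in the sources used here. Total counts per library, in order of replicate, were 37187794, 27763604 and 31976287 for WT without H89, 20331301, 21922022 and 20223311 for WT with H89, 18533717, 17562754 and 18328153 for S434A without H89, and 21028581, 20064967 and 22648485 for S434A with H89. Of the genes counted, 14435 passed the filter on low counts and were tested.

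HDAC1 (ENSG00000116478.12_7, hg19 chromosome 1, 32757684 to 32799236) was expressed in all 12 libraries. Its counts scaled to library size (CPM) were 682, 704 and 679 in WT without H89, 693, 665 and 732 in WT with H89, 713, 752 and 659 in S434A without H89, and 622, 680 and 552 in S434A with H89. The group means were 688 ± 13.6, 697 ± 33.8, 708 ± 46.8 and 618 ± 64.0 CPM (SD, n = 3). No comparison passed the test for HDAC1, with log2 fold changes of 0.04 for S434A against WT without H89, 0.02 for H89 in WT, -0.20 for H89 in S434A (adjusted p = 0.0572) and -0.17 for S434A against WT with H89. The sign for the first 2 depends on the scaling, at -0.02 and -0.13 with RLE factors, and for H89 in S434A the change was -0.29 with RLE factors and passed at under 2-fold (adjusted p = 0.0112, against 0.00402 to 0.438 over the other scalings, DESeq2 and trend removal). Once each library's trend on GC content and gene length was removed, HDAC1 passed for H89 in WT at 0.24 and for the difference of H89 effects between genotypes at -0.31, below a 2-fold change in both. Counts per gene do not show the mutation, so the genotype labels were not checked by them.

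The libraries differed in make-up along with their groups. Mitochondrially encoded mRNAs took 1.48 to 1.51% of counts in WT without H89, 4.91 to 6.26% in WT with H89, 5.57 to 5.94% in S434A with H89, and 7.02, 4.09 and 3.16% in the 3 replicates of S434A without H89. Ribosomal protein genes took 18.3 to 18.8% of counts in WT without H89, 6.73 to 7.11% in WT with H89, 7.25 to 7.26% in S434A with H89, and 8.64, 8.73 and 10.6% in S434A without H89. ALB, the gene of serum albumin, took 0.293% of counts in replicate 1 of S434A without H89 against 1.82 and 2.43% in replicates 2 and 3. Across genes, which are not independent replicates, expression relative to the mean of all libraries rose with GC content in S434A without H89 (Spearman rho 0.82, 0.72 and 0.13) and fell with it in the other 9 libraries (-0.45 to -0.06). The biological coefficient of variation within a group was 0.0191 in WT without H89, 0.0733 in WT with H89, 0.351 in S434A without H89 and 0.0547 in S434A with H89. A chi-square over genes compared the counts of 2 libraries, and larger values mean more spread beyond counting. Per degree of freedom it was 1.62 to 2.04 between replicates of WT without H89. It was 5.94 to 9.34, 34.2 to 164 and 3.93 to 5.12 in the other groups, in the same order. The series states biological replicates, but counts cannot show whether the close libraries of WT without H89 came from separate cultures.

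**Figure D1:**
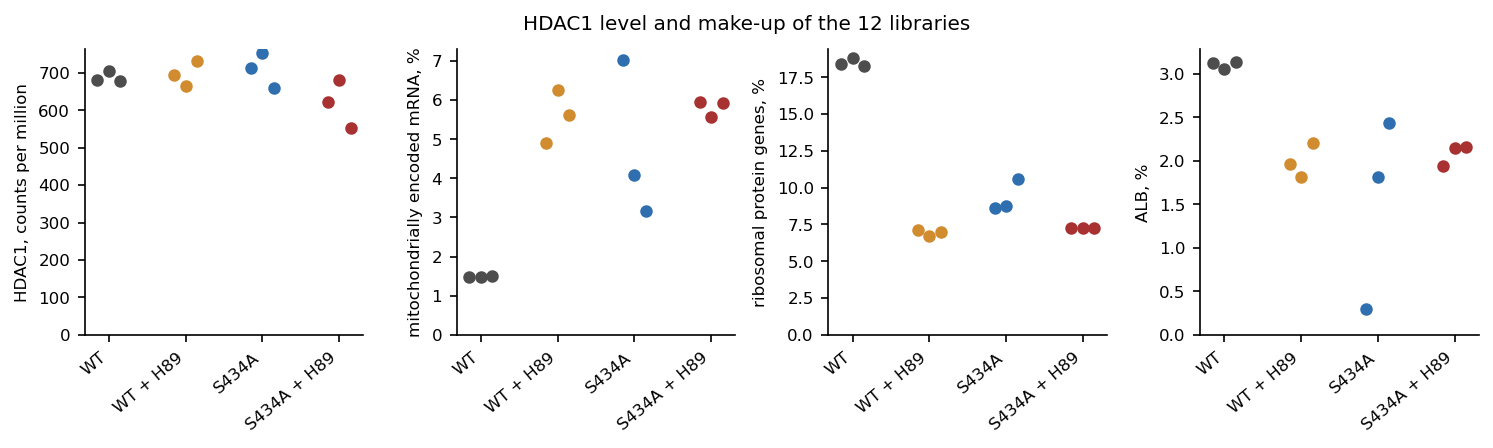
HDAC1 level (CPM) and the percent of counts from mitochondrially encoded mRNAs, ribosomal protein genes and ALB, by group. Each point is 1 library (n = 3 per group). Ribosomal protein genes take 18.3 to 18.8% in WT without H89 and at most 10.6% in the other 9 libraries.

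**Figure D2:**
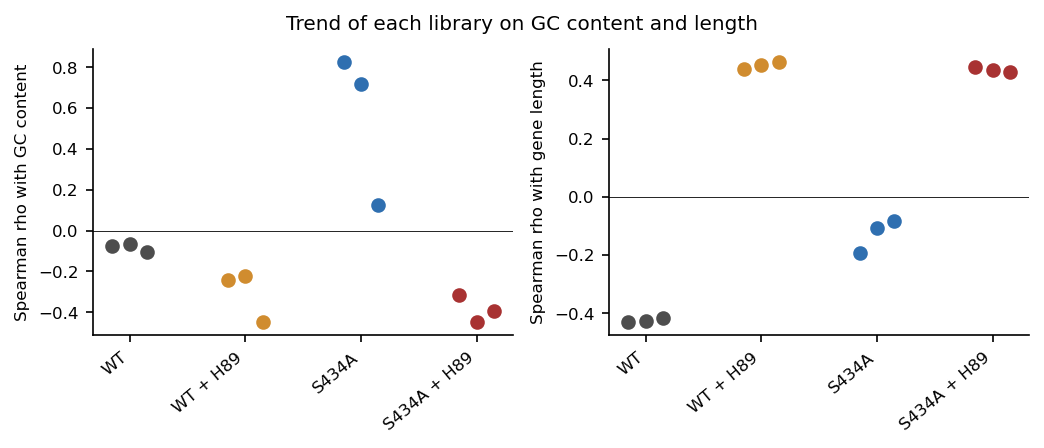
Spearman rho, across genes, of each library's expression relative to the mean of all libraries with GC content (left) and gene length (right). Each point is 1 library. The rho with GC content runs from 0.13 to 0.82 within S434A without H89.

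S434A vs WT without H89 asks what the mutation changed in untreated cells. Among the largest rises were HSPG2 (ENSG00000142798.20_10, hg19 chromosome 1, 22148737 to 22263803), the basement membrane proteoglycan perlecan, LAMA5, a laminin chain, and LRP1, an endocytic receptor. HSPG2 was at 17.6 ± 0.340 CPM in WT and 111 ± 47.9 CPM in S434A (SD, n = 3), a log2 fold change of 2.66 (SE 0.28, adjusted p = 1.67e-05). LAMA5 and LRP1 rose by 2.42 and 2.36 on the log2 scale. The cytolinker gene EPPK1 rose by 2.21, the focal adhesion gene TNS4 by 2.15, the endosialin gene CD248 by 2.14 and CILP2 by 2.09. A further 3 mRNAs, encoded by the mitochondrial genome, completed the 10 largest rises, MT-ND5 at 2.55, MT-ND1 at 2.23 and MT-ATP8 at 2.14, and mitochondrially encoded counts differed between the libraries as given above. Much of the rise of HSPG2, LRP1, LAMA5 and EPPK1 went with the GC and length trends, on whose removal they were at 1.25, 1.31, 0.91 and 0.98, the last 2 under 2-fold, and CILP2 was at 1.21.

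The largest falls were those of RPS3A at -2.51, HIGD1A at -2.42, the cysteine protease inhibitor CSTA (cystatin A) at -2.37, the proteasome subunit PSMA4 at -2.36, MIX23 at -2.34, the ESCRT gene CHMP5 at -2.33, LSM3 at -2.33, the calmodulin gene CALM2 at -2.32, RPL7 at -2.32 and UQCRHL at -2.31. CSTA fell from 16.9 ± 1.03 to 3.27 ± 0.366 CPM (SE of the log2 change 0.16, adjusted p = 7.07e-07). These falls too were smaller with the GC and length trends removed, with CSTA, MIX23 and CHMP5 at -1.31 and HIGD1A at -1.56, all still past 2-fold. RPS3A, RPL7, UQCRHL and CALM2 have pseudogene copies or near-identical relatives with which reads can be shared, so their values are uncertain. The share of counts from ribosomal protein genes differed between these groups in the same direction.

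Several lists of genes fixed in advance were tested in this comparison. Of 24 SRF and YAP targets measured, which include genes of the actin cytoskeleton, 17 rose and 4 fell (17 and 4 adjusted over the list alone), with THBS1 at 1.35 (SE 0.10), VCL at 0.91, FLNA at 1.82 and AXL at 1.47. The list was higher than other genes (camera adjusted p = 0.00276, but adjusted p = 0.631 with an estimated correlation). Of 16 genes of fatty acid and triglyceride synthesis 12 rose and none fell (12 and 0 adjusted over the list alone), among them FASN at 1.94 (SE 0.22), ACACB at 1.27, ACACA at 0.92 and SCD at 0.82 (adjusted p = 0.00569, and adjusted p = 0.631 with an estimated correlation). Of 18 epithelial and mesenchymal genes 11 rose and 2 fell, with fibronectin, FN1, at 2.03 (SE 0.16) and the N-cadherin gene CDH2 at 0.77 (adjusted p = 0.0499, and adjusted p = 0.631 with an estimated correlation). Markers of other cell types rose as well, 3 of 4 for blood and endothelium (median log2 fold change 0.66) and the 1 fibroblast marker measured (0.87), without passing as lists. Of 21 glycolysis genes 14 rose and 4 fell, with HK2 at 1.02 and LDHA at -0.49 (adjusted p = 0.0499, and adjusted p = 0.778 with an estimated correlation). The counts for epithelial and mesenchymal genes and for glycolysis were the same adjusted over the list alone. These 2 lists were at the edge of the test, and neither passed with RLE factors or without replicate 1 or 3 of WT or replicate 2 of S434A, which left 3 lists of 5. All 13 mitochondrially encoded mRNAs changed, 12 upwards, MT-CO2 by 1.03, and 1 downwards (adjusted p = 0.00276, and adjusted p = 0.707 with an estimated correlation). After removal of each library's trend on GC content and length only this last list passed, at the preset correlation, while SRF and YAP targets (adjusted p = 0.176), fatty acid and triglyceride synthesis (0.252), epithelial and mesenchymal genes (0.0936) and glycolysis (0.680) did not, and LDHA, at -0.22, no longer passed. FASN was then at 0.68, ACACB at 0.49, FLNA at 0.66, AXL at 0.98 and HK2 at 0.82, which are under 2-fold, ACACA at 0.45, VCL at 0.58 and MT-CO2 at 1.84. Of the fatty acid and triglyceride synthesis genes 9 were then higher and 3 lower, with a median log2 fold change of 0.35 against 0.73 before.

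Members of the HDAC family moved in both directions, 5 up and 5 down of 15 (5 and 5 adjusted over the list alone, camera adjusted p = 0.702). HDAC7, HDAC6 and HDAC4 rose by 1.42 (SE 0.17), 1.12 and 1.03, and HDAC3 fell by 0.70. When the GC and length trends were removed, 3 of the family were higher and 9 lower, HDAC7 was at 0.30, HDAC6 at 0.29 and HDAC4 at 0.09, and HDAC4 no longer passed. Of 18 cAMP, PKA and CREB-responsive genes 7 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.505). NR4A1, EGR1 (hg19 chromosome 5, 137801168 to 137804992) and CRTC2 rose by 1.15, 0.99 and 1.04 and CREM fell by 1.19. NR4A1 was at 0.27 and no longer passed after removal of the trends, and CRTC2 and CREM were under 2-fold at 0.74 and -0.82.

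By edgeR's quasi-likelihood test, 1677 genes were higher and 1635 lower in S434A without H89 (fold change over 2 and adjusted p under 0.05 among 14435 genes), and 8418 genes had an adjusted p under 0.05 at any fold. GC content and gene length together accounted for 38.3% of the variance of the log2 fold changes across genes. With each library's trend on GC content and length removed, 745 genes were higher and 895 lower, and 31.6% of the 3312 genes called above were called in the same direction. Fitting only the 6 libraries compared gave 2397 higher and 921 lower, so the balance of directions depends on the fit.

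H89 effect in WT asks what H89 changed in cells with wild-type HDAC1. Among the named genes, and before removal of the GC and length trends, CSTA showed the largest fall. It went from 16.9 ± 1.03 to 0.772 ± 0.182 CPM (SD, n = 3), a log2 fold change of -4.43 (SE 0.18, adjusted p = 7.64e-09). HP, the haptoglobin gene (ENSG00000257017.4, hg19 chromosome 16, 72088491 to 72094954), fell from 2411 ± 64.7 to 193 ± 16.9 CPM, a change of -3.64 (SE 0.13, adjusted p = 5.16e-09). HP shares reads with its relative HPR and is uncertain to that extent. The interleukin-8 gene CXCL8, the trypsin inhibitor SPINK1 and the lipase-like enzyme gene AADAC fell by 3.56, 3.40 and 3.38. The keratin KRT15 was at -3.70, the calcium-binding protein gene S100A2 at -3.64, AIF1 at -3.62 and CD3D at -3.29, each from under 5 CPM. RPL9, whose reads can be shared with pseudogenes, was at -3.42. All these falls hold the GC and length trends of the libraries.

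Before removal of the GC and length trends, the nuclear noncoding RNA MALAT1 (hg19 chromosome 11, 65265159 to 65273987) showed the largest rise with H89 in WT among the named genes. It went from 10.6 ± 1.02 to 168 ± 42.2 CPM (log2 fold change 3.98, SE 0.53, adjusted p = 5.72e-05). CEMIP, which takes part in hyaluronan breakdown, rose by 3.26 (SE 0.16). The other large rises were those of ALMS1 at 3.50, BIRC6 at 3.37, MT-ND5 at 3.22, RFX7 at 3.16, FRYL at 3.14, MYCBP2 at 3.11 and BLTP1 at 3.10. Removal of the GC and length trends lowered BIRC6 to 2.12, FRYL to 1.93, MYCBP2 to 1.94 and BLTP1 to 1.87. Gene length correlated with the log2 fold change in this comparison at a Spearman rho of 0.47 across genes.

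Of 24 hepatocyte secreted proteins 18 fell and 1 rose with H89 in WT (19 and 1 adjusted over the list alone). The apolipoprotein gene APOA1 (hg19 chromosome 11, 116706467 to 116708338) fell from 8474 ± 2.51 to 2147 ± 47.2 CPM, a log2 change of -1.98 (SE 0.05). AMBP, APOA2 and APOC3 fell by 1.60, 1.40 and 1.31, and by 0.96, 0.53 and 0.59 with the GC and length trends removed. The list was lower than other genes (camera adjusted p = 0.000117, and adjusted p = 0.102 with an estimated correlation). Of 12 acute phase and complement genes 6 fell and 2 rose (6 and 2 adjusted over the list alone), with ORM1 at -1.65, ORM2 at -1.66 and SERPINA3 at -1.14 (adjusted p = 0.0051, and adjusted p = 0.102 with an estimated correlation). ORM1 and ORM2 are near-identical and can share reads.

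Fatty acid and triglyceride synthesis genes rose, 13 of 16 with none lower (14 and 0 adjusted over the list alone). FASN, fatty acid synthase, rose from 231 ± 4.63 to 1526 ± 210 CPM (log2 fold change 2.72, SE 0.23), SCD by 1.74, ACACA by 1.53 and ACLY by 1.28 (adjusted p = 0.000849, and adjusted p = 0.289 with an estimated correlation). Of 30 genes of PKA subunits and cAMP signalling 23 rose and 4 fell (23 and 4 adjusted over the list alone), with AKAP13 at 2.34, the coactivator CREBBP at 2.28, ADCY9 at 1.72 and the PKA inhibitor gene PKIG at -1.35 (adjusted p = 0.0146, and adjusted p = 0.102 with an estimated correlation). Of 33 genes of class I HDAC corepressor complexes 21 rose and 5 fell (21 and 5 adjusted over the list alone), with SIN3A at 1.51, PHF21A at 1.39, SAP18 at -1.62 and DNTTIP1 at -1.01 (adjusted p = 0.0382, and adjusted p = 0.289 with an estimated correlation). Of 18 cAMP, PKA and CREB-responsive genes 9 rose and 7 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.875). PCK1, a gluconeogenic enzyme, fell by 1.07 and ID1 by 0.76, while EGR1 rose by 1.37 and CRTC2 by 1.23. ID1 was at 0.00 and no longer passed after removal of the GC and length trends. All 13 mitochondrially encoded mRNAs changed, 12 upwards and MT-ND3 by -0.83 (adjusted p = 0.0145, and adjusted p = 0.667 with an estimated correlation). After removal of the trends the lists of acute phase genes (adjusted p = 0.339), corepressor complexes (0.316) and PKA subunits (0.101) no longer passed, nor did MT-ND3 at -0.14. Changes that then fell short of 2-fold were those of ORM1 at -0.77, ORM2 at -0.78, ACACA at 0.73, SIN3A at 0.72, PHF21A at 0.68, DNTTIP1 at -0.33 and PKIG at -0.85. FASN was at 1.59, CREBBP at 1.41, AKAP13 at 1.27 and ADCY9 at 1.01. For fatty acid and triglyceride synthesis 12 genes were then higher and 2 lower, and the median log2 fold change went from 1.27 to 0.50 (adjusted p = 0.0212).

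**Figure D3:**
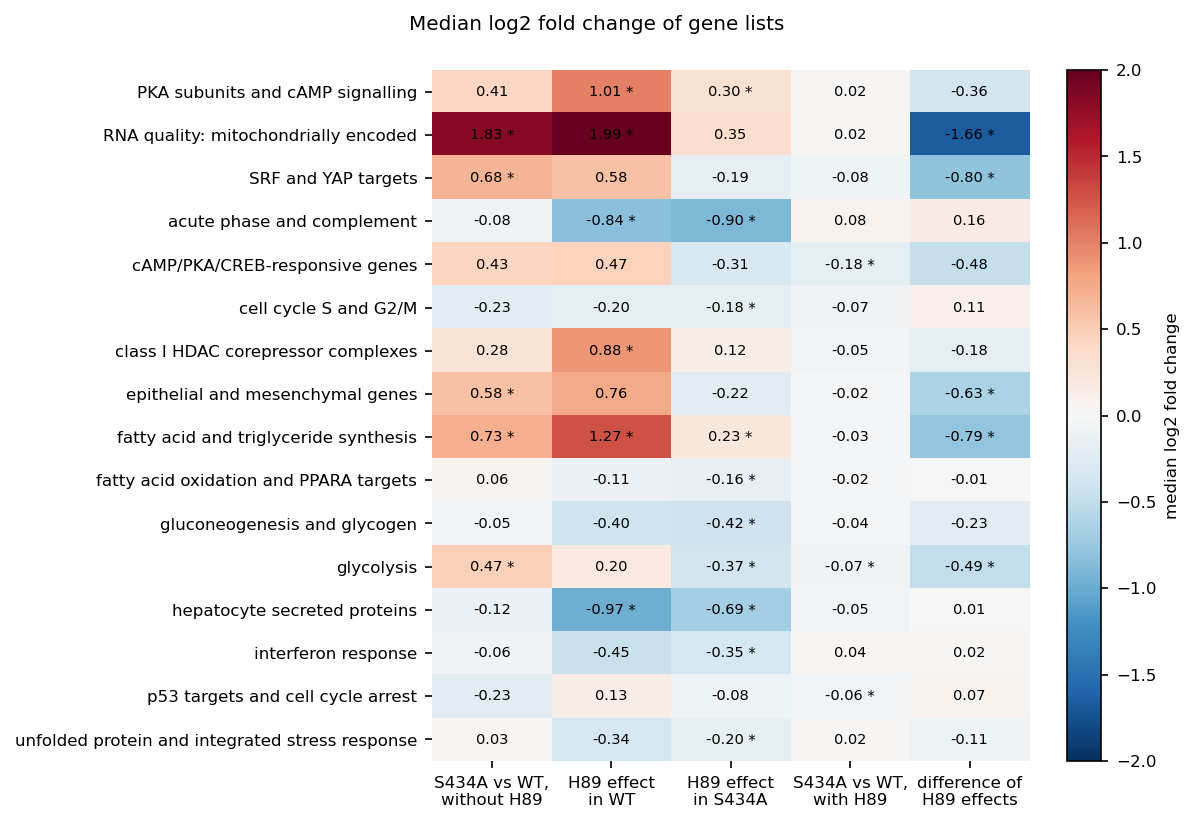
Median log2 fold change of the measured members of each gene list in the 5 comparisons, for the 16 lists past a camera adjusted p of 0.05 in at least 1 of them (star: that comparison). Hepatocyte secreted proteins have medians of -0.97 and -0.69 for H89 in WT and in S434A.

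By edgeR's test, 3201 genes rose and 2285 fell with H89 in WT, and 10065 had an adjusted p under 0.05 at any fold. The median log2 fold change over all genes was 0.20 with TMM scaling and 0.05 with RLE size factors, under which 2579 genes rose and 2713 fell, so directions near 0 depend on the scaling. After the trends were removed, 1983 rose and 2116 fell.

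H89 effect in S434A asks the same of cells with the mutant. The tubulin gene TUBA1A fell by 2.44 on the log2 scale (SE 0.22, adjusted p = 3.17e-05) and PLG, the plasminogen gene (ENSG00000122194.19_4, hg19 chromosome 6, 161123270 to 161175129), by 2.39, from 28.9 ± 4.99 to 5.50 ± 0.976 CPM (SD, n = 3, SE 0.16). HAL, histidine ammonia-lyase, fell by 2.32, the heme-binding plasma protein HPX by 2.07, HP by 2.02 and the glycine methyltransferase GNMT by 1.91. GFRA3 fell by 2.11, KRTAP3-1 by 2.09, LCK by 2.06 and FUT1 by 2.06, each from under 5 CPM. The rises were led by ANGPTL1 at 2.81 (SE 0.37, adjusted p = 0.00028), DMXL2 at 2.79, BRWD3 at 2.58, FRYL at 2.56, MYO9A at 2.55, ZBTB38 at 2.53, DOP1A at 2.51, USF3 at 2.45, BLTP1 at 2.44 and RFX7 at 2.43. These 10 rises were smaller, at 1.12 (BLTP1) to 1.75 (ANGPTL1), with the GC and length trends removed. The falls above are given with the trends left in. Spearman rho of the log2 fold change with GC content was -0.68 across genes in this comparison.

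Of 24 hepatocyte secreted proteins 16 fell and none rose with H89 in S434A (16 and 0 adjusted over the list alone), with APOC3 at -1.17, APOA1 at -1.16, the fibrinogen chain FGA at -1.04 and AMBP at -0.71. Of 12 acute phase and complement genes 9 fell and none rose (9 and 0 adjusted over the list alone), with LCN2 at -1.58, ORM2 at -1.09 and ORM1 at -0.99. These were the only lists that held with an estimated correlation in any of the 5 comparisons (camera adjusted p = 1.73e-11 and 2.16e-08, and adjusted p = 0.00455 for both with an estimated correlation). After removal of the GC and length trends 18 and 10 of their members fell, and 1 acute phase gene rose, while APOA1, APOC3 and ORM2 were under 2-fold at -0.79, -0.79 and -0.71, and ORM1 and AMBP were at -0.60 and -0.31.

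Genes of gluconeogenesis and glycogen fell, 8 of 13 with 3 higher (8 and 3 adjusted over the list alone). G6PC1, glucose-6-phosphatase, fell from a mean of 79.3 to 26.7 CPM (log2 fold change -1.57, SE 0.15), PCK1 from 128 ± 7.11 to 52.0 ± 8.25 CPM (-1.30, SE 0.11), PCK2 by 1.23 and SLC37A4 by 0.71 (adjusted p = 0.0156, and adjusted p = 0.148 with an estimated correlation). Of 21 glycolysis genes 12 fell and 1 rose (13 and 1 adjusted over the list alone), with PGK1 at -0.69 and TPI1 at -0.60 (adjusted p = 0.0014, and adjusted p = 0.470 with an estimated correlation). Of 32 cell cycle genes 16 fell and 1 rose (16 and 1 adjusted over the list alone), with BIRC5 at -0.84, E2F1 at -0.80, RRM2 at -0.72 and CCNE1 at -0.57 (adjusted p = 0.0156, and adjusted p = 0.148 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response 12 fell and 3 rose (12 and 4 adjusted over the list alone). The serine synthesis gene PHGDH was at -1.32, SHMT2 at -0.84, PDIA4 at -0.56 and CREB3L2 at 0.54 (adjusted p = 0.0156, and adjusted p = 0.306 with an estimated correlation).

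Of 17 genes of fatty acid oxidation and PPARA targets 8 fell and 2 rose with H89 in S434A (8 and 2 adjusted over the list alone), with ACADVL at -0.92, ECI1 at -0.71, SLC25A20 at -0.67 and HADHA at -0.47 (adjusted p = 0.0236, and adjusted p = 0.148 with an estimated correlation). Of 23 interferon response genes 11 fell and 6 rose (11 and 6 adjusted over the list alone), with HLA-B, whose reads can be shared with related genes, at -1.38 (adjusted p = 0.0281, and adjusted p = 0.168 with an estimated correlation). Fatty acid and triglyceride synthesis genes rose, 6 of 16 with none lower (6 and 0 adjusted over the list alone), with SCD at 0.87 and ACACA at 0.51 (adjusted p = 0.0369, and adjusted p = 0.450 with an estimated correlation). Of 30 genes of PKA subunits and cAMP signalling 13 rose and 3 fell (13 and 3 adjusted over the list alone), with the phosphodiesterases PDE7A at 1.20 and PDE8A at 1.15 (adjusted p = 0.0437, and adjusted p = 0.168 with an estimated correlation). PDE7A was at 0.12 and no longer passed after removal of the trends, nor did the lists of glycolysis (adjusted p = 0.0950), unfolded protein and integrated stress response (0.0595) and interferon genes (0.348). PCK2 and PDE8A were then under 2-fold at -0.90 and 0.57. PGK1 and RRM2 were instead larger and past 2-fold, at -1.41 and -1.39. Smaller changes were left for TPI1 (-0.25), E2F1 (-0.44), CCNE1 (-0.34), SLC37A4 (-0.46), SHMT2 (-0.55), PDIA4 (-0.29), ECI1 (-0.42), SLC25A20 (-0.44) and ACACA (0.19).

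**Figure D4:**
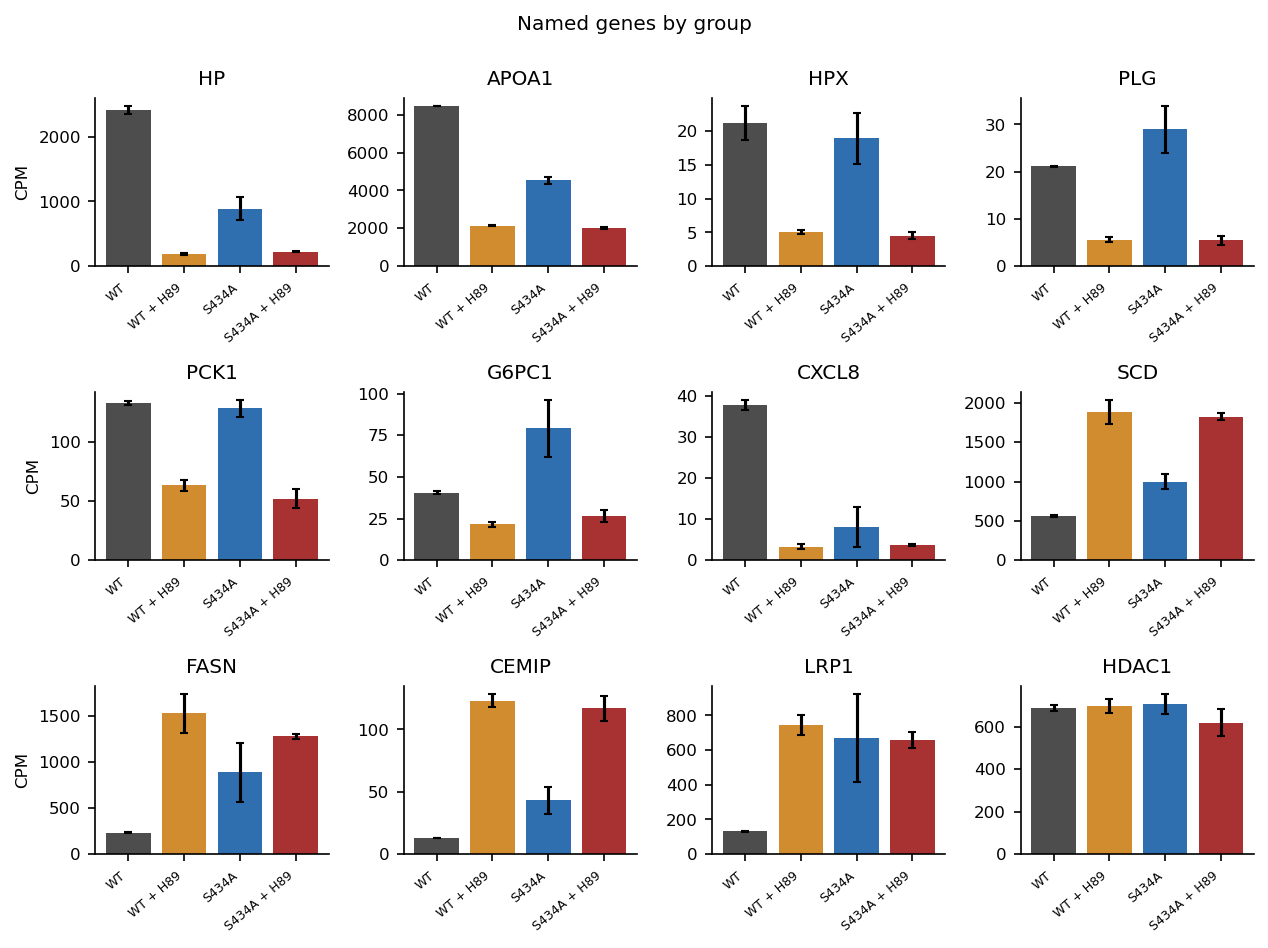
Mean CPM of 12 named genes in the 4 groups, with error bars of 1 SD (n = 3). HP is at 2411 CPM in WT without H89 and at 889 CPM in S434A without H89, and at 193 and 220 CPM with H89.

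By edgeR's test, 2201 genes rose and 339 fell with H89 in S434A, and 7504 had an adjusted p under 0.05 at any fold. The counts rested on the replicates of S434A without H89: without replicate 1 there were 1284 rises and 298 falls, without replicate 3 there were 3067 and 437, and with only the 6 libraries compared there were 584 and 248. Leaving out replicates 1, 2 or 3 of S434A with H89 gave 2143, 1635 and 1711 genes against 2540. After removal of the trends 782 genes were called, 348 of them higher, and 17.9% of the genes called above were called in the same direction. Median log2 fold changes over all genes were 0.01 with TMM and -0.11 with upper-quartile factors.

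S434A vs WT with H89 asks whether the genotypes differed in treated cells. No gene passed the test. By edgeR, 589 genes had an unadjusted p under 0.05 and 0 an adjusted p under 0.05 among 14435, limma-voom called 0, and DESeq2 called 1. That gene was EVA1A-AS (log2 fold change 1.18, SE 0.24, DESeq2 adjusted p = 0.00821). It is an antisense gene that was counted without regard to strand, so reads from the opposite strand are not excluded. The main fit shares 1 spread with S434A without H89, the most variable group. By edgeR with only the groups compared, 1593 genes had an unadjusted p under 0.05 and 0 an adjusted p under 0.05. With limma-voom and a weight per group the numbers were 1830 and 3. With the GC and length trends removed and replicate 1 of S434A without H89 left out, they were 2189 and 78, at any fold. The median size of the log2 difference over all genes was 0.10, and the 9 pairs of a WT and an S434A library with H89 correlated at 0.992 to 0.995 across genes. Pairs within these 2 groups correlated at 0.993 to 0.995. By chi-square per degree of freedom, replicate 3 of WT and replicate 2 of S434A were each other's nearest library (2.99). That WT library was at 8.75 and 9.34 with its own group. Replicate 2 of WT was nearest to replicate 1 of S434A (4.75). Replicate 1 of WT and replicates 1 and 3 of S434A were nearest to their own group. The treated libraries did not fully sort by genotype, and their labels were not tested.

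By camera, which compares a list with the other genes, 3 lists were lower in S434A than in WT with H89, although no member of them passed the test over all genes. The number of lists hung on single libraries, at 0 without replicate 3 of S434A, 1 without replicate 1 of WT and 6 without replicate 2 of WT, and it was 5 with the GC and length trends removed. The median log2 difference was -0.18 for 18 cAMP, PKA and CREB-responsive genes (camera adjusted p = 0.00504, and adjusted p = 0.423 with an estimated correlation), of which ID1 was at 0.23 (SE 0.08) and CEBPB at 0.00 (SE 0.13). It was -0.07 for 21 glycolysis genes (adjusted p = 0.015, and adjusted p = 0.634 with an estimated correlation), with ENO1 at -0.11 (SE 0.10) and GAPDH at -0.05 (SE 0.07). It was -0.06 for 23 p53 targets and cell cycle arrest genes (adjusted p = 0.0444, and adjusted p = 0.423 with an estimated correlation), with GDF15 at -0.33 (SE 0.10) and FDXR at -0.01 (SE 0.05). Tested against no change by fry, the unadjusted p was 0.0305, 0.350 and 0.0594 for these lists in the same order. Adjusted over the list alone, 0 genes of the first 2 lists passed, and of the p53 list TP53I3 was higher by 0.46 while GADD45A, BBC3 and GDF15 were at -0.40, -0.34 and -0.33. EVA1A-AS, TP53I3, GADD45A and BBC3 fall outside the rule for named genes and were picked out after their values were seen. In tests on simulated data for this comparison, 94% of 50 genes changed by 3-fold and 36% of 50 changed by 2-fold were called.

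The difference of H89 effects between genotypes asks whether the response to H89 differed between S434A and WT. It is the effect in S434A minus that in WT, and it was tested as an interaction. The same value is S434A vs WT with H89 minus S434A vs WT without H89. As the genotypes differed little with H89 (median size 0.10), it largely repeats S434A vs WT without H89 with its sign turned. HSPG2, for instance, was at 2.66 there and at -2.91 here. It is therefore not separate evidence. The smallest p-values among positive differences were those of RPS20 (1.37), DYNLL1 (1.44), RPL27A (1.42), APOA2 (1.13) and SAP18 (1.45), each with an SE of 0.06 to 0.08 and an adjusted p of 7.46e-06. DYNLL1, a dynein light chain, went from 414 ± 10.2 to 120 ± 1.13 CPM with H89 in WT and from 169 ± 9.49 to 133 ± 3.39 CPM in S434A. Reads of RPS20 and RPL27A can be shared with pseudogenes. SAP18 was at 0.52 and no longer passed after removal of the GC and length trends. Among negative differences, EP300 (hg19 chromosome 22, 41488596 to 41576081), a histone acetyltransferase, was at -1.84 (SE 0.11, adjusted p = 7.46e-06), HECTD4 at -1.80, SPTBN1 at -1.19, the chromatin remodeller CHD8 at -1.30 and FRAS1 at -2.10. Removal of the trends left RPS20 at 0.89, APOA2 at 0.66, HECTD4 at -0.89, SPTBN1 at -0.54 and CHD8 at -0.70, under 2-fold. EP300 went from 12.9 ± 0.386 to 69.5 ± 1.18 CPM with H89 in WT and from 41.3 ± 4.40 to 62.0 ± 1.48 CPM in S434A.

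Of 24 SRF and YAP targets 17 had a more negative H89 effect in S434A and 4 a more positive one (17 and 4 adjusted over the list alone), with FLNA at -1.95, THBS1 at -1.51, AMOTL2 at -1.38 and VCL at -1.01 (camera adjusted p = 0.00252, and adjusted p = 0.555 with an estimated correlation). For fatty acid and triglyceride synthesis 10 of 16 were more negative and none more positive (11 and 0 adjusted over the list alone), with FASN at -2.20, ACLY at -1.09, ACACA at -1.03 and SCD at -0.87 (adjusted p = 0.00801, and adjusted p = 0.555 with an estimated correlation). For the mitochondrially encoded mRNAs 12 of 13 were more negative, MT-ND5 by -2.53 (SE 0.49), and MT-ND3 was at 0.63 (adjusted p = 0.00801, and adjusted p = 0.691 with an estimated correlation). Of 21 glycolysis genes 13 were more negative and 3 more positive (14 and 4 adjusted over the list alone), with HK2 at -1.25 and the glucose transporter SLC2A3 at -0.98 (adjusted p = 0.0217, and adjusted p = 0.691 with an estimated correlation). Of 18 epithelial and mesenchymal genes 7 were more negative and none more positive (7 and 0 adjusted over the list alone), with FN1 at -2.24 and CDH2 at -0.86 (adjusted p = 0.0336, and adjusted p = 0.555 with an estimated correlation). The 1 fibroblast marker measured was more negative too (-0.95), as were 2 of 4 for blood and endothelium (median -0.90), without passing as lists. With the GC and length trends removed, 9 of the 18 epithelial and mesenchymal genes were more negative and 2 more positive. After removal of the GC and length trends only the mitochondrially encoded list passed, at the preset correlation, and MT-ND3 was at -0.19 without passing. FASN was then at -0.84, ACLY at -0.82, ACACA at -0.54, FLNA at -0.71, VCL at -0.67 and AMOTL2 at -0.66, under 2-fold, while SLC2A3 at -1.09, SCD at -1.03 and CDH2 at -1.09 were past it.

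By edgeR's test, 1696 genes had a more positive and 1795 a more negative H89 effect in S434A than in WT. Removal of the GC and length trends gave 1021 and 868, and 1208 of the 3491 genes called above (34.6%) were called in the same direction. The fit shares 1 spread among the groups although that of S434A without H89 was far larger, and on simulated data with the groups' own spreads 89 of 14025 unchanged genes were called for S434A vs WT without H89, 85 for H89 effect in S434A and 28 for the difference of H89 effects. These made up 42.4, 41.3 and 23.3% of the calls in simulations with 200 changed genes. At any fold, as in the counts of list members, 330, 336 and 45 unchanged genes had an adjusted p under 0.05, in the same order. The simulated genes were independent and held no GC or length trend, so errors shared across genes were not covered.

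The H89 effect in WT and the H89 effect in S434A share no library, but a bias common to the libraries with H89 would enter both. H89 raised 1260 genes in both genotypes, against 488 for independent lists. It lowered 232, against 53.7 (Fisher's exact test, p = 1.08e-107 for the falls). The test takes genes as independent, which they are not, so its p-value does not measure replication. Both effects went with gene length (Spearman rho 0.47 in WT and 0.37 in S434A). Part of the excess may come from such trends. A batch shared by the libraries with H89 cannot be told apart from H89 here. HP, HPX, HAL, APOA1 and PCK1 were lower and MALAT1, CEMIP, FRYL and RFX7 were higher with H89 in both genotypes. Calls went opposite ways for 5 genes, METTL18, ORC4, MRPL1, SPRED3 and ENSG00000243818, which were picked out after their values were seen. Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.586 and Spearman's rho 0.559. With the GC and length trends removed, 598 genes were shared in direction and r was 0.684.

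The overlap of the S434A effect with the H89 effect in WT asks whether the mutation and H89 moved the same genes. Both effects raised 1238 genes, among them HSPG2, LAMA5, LRP1, FASN and FN1, against 372 for independent lists, and both lowered 1111, among them CSTA, HP and CXCL8, against 259. MUC5B alone was called in opposite directions, and it was picked out after its values were seen. Pearson's r across genes was 0.733, against 0.474 for simulated unchanged groups set against the same controls, and the covariance was 0.688 against a simulated 0.0301, a difference of 0.658. Simulated unchanged groups gave 0 shared calls in 5 fits. These draws used a pooled spread, and with each group's own spread r was 0.171 and the covariance 0.00906. Genes were drawn independently, without GC or length trends and without a shift of WT without H89. Such a shift would move both effects alike, so the simulation cannot bound what the shared controls give. Both comparisons use the 3 libraries of WT without H89, which cannot be split into 2 sets of 2 libraries. Part or all of the excess over independent lists may therefore come from the shared controls. For S434A vs WT with H89, which shares libraries with the opposite sign, the covariance with the H89 effect in WT was -0.0684 against a simulated -0.0324. With the GC and length trends removed 1360 genes were shared in direction and r was 0.842.

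**Figure D5:**
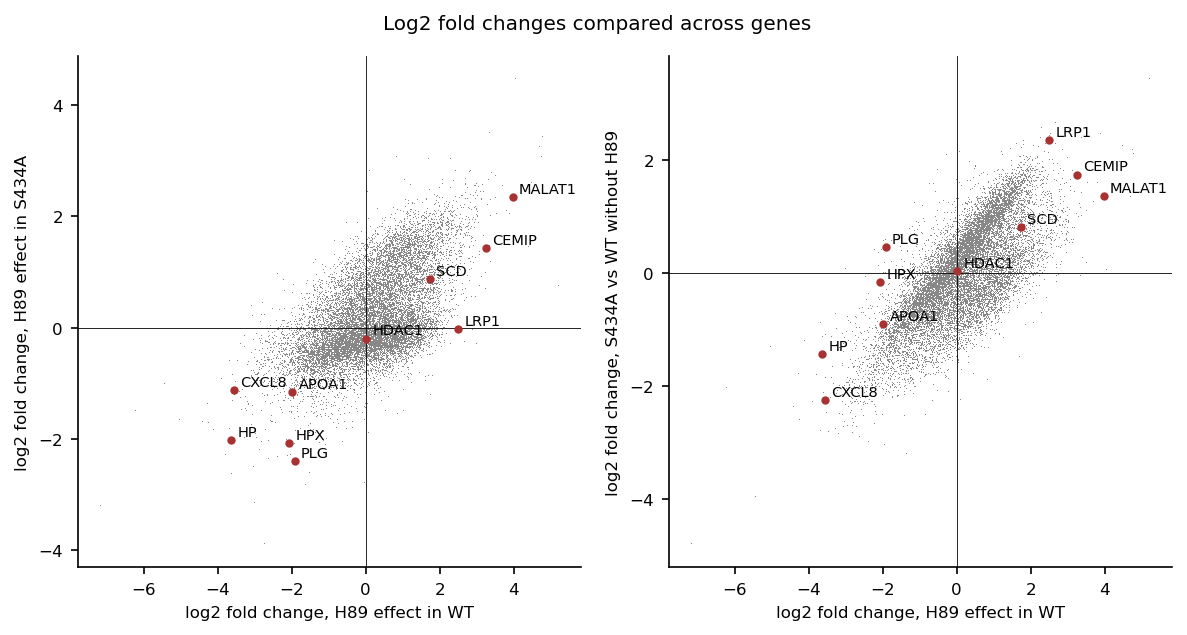
Log2 fold change of each of 14435 genes for H89 in WT (horizontal) against H89 in S434A (left) and S434A against WT without H89 (right). Each small point is a gene and red points are named genes. Pearson's r across genes is 0.586 on the left and 0.733 on the right.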

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

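Several tests were chosen only after the results were seen. These were the tests on a swap of libraries, on a batch and on a shift of WT without H89 alone. The tests on the share of calls left after the GC and length trends were removed, and the splits of the libraries for the comparisons of 2 groups, were also chosen then.

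A difference between the genotypes in the effect of H89, tested as an interaction, singled out the results of this part. As given above, this difference largely repeats S434A vs WT without H89 with its sign turned. It was found for 3491 genes. Among the lists it was found for SRF and YAP targets (camera adjusted p = 0.00252), fatty acid and triglyceride synthesis (0.00801), mitochondrially encoded mRNAs (0.00801), glycolysis (0.0217) and epithelial and mesenchymal genes (0.0336), each with a lower H89 effect in S434A. None of the 5 passed with an estimated correlation (adjusted p = 0.555 to 0.691). After removal of the GC and length trends the mitochondrially encoded mRNAs passed at the preset correlation, and the others did not (0.123, 0.367, 0.541 and 0.0746 for SRF and YAP targets, fatty acid and triglyceride synthesis, glycolysis, and epithelial and mesenchymal genes).

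The log2 H89 effect in S434A minus that in WT was negative for the following named genes. Differences beyond a 4-fold change were those of HSPG2 (-2.91), LAMA5 (-2.57), LRP1 (-2.54), MT-ND5 (-2.53), FN1 (-2.24), EPPK1 (-2.24), CILP2 (-2.22), FASN (-2.20), MT-ND1 (-2.11), FRAS1 (-2.10), MT-ATP8 (-2.05) and CD248 (-2.02). Differences of 2-fold to 4-fold were those of FLNA (-1.95), TNS4 (-1.94), EP300 (-1.84), CEMIP (-1.82), HECTD4 (-1.80), ADCY9 (-1.74), CREBBP (-1.71), HDAC7 (-1.57), AKAP13 (-1.53), THBS1 (-1.51), NR4A1 (-1.47), FUT1 (-1.41), AMOTL2 (-1.38), AXL (-1.35), CREB3L2 (-1.33), CHD8 (-1.30), EGR1 (-1.27), SIN3A (-1.27), HK2 (-1.25), ACACB (-1.25), CRTC2 (-1.21), HDAC6 (-1.20), SPTBN1 (-1.19), RXRA (-1.17), HDAC4 (-1.15), ACLY (-1.09), ACACA (-1.03), MT-CO2 (-1.03), GFRA3 (-1.02) and VCL (-1.01). Smaller ones were those of PHF21A (-0.99), HNF4A (-0.98), SLC2A3 (-0.98), LSS (-0.94), FOXA1 (-0.87), SCD (-0.87), CDH2 (-0.86), CYP1A1 (-0.75), G6PC1 (-0.66), CEBPB (-0.56) and ENO1 (-0.36).

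It was positive for these. Beyond 4-fold were SPINK1 (2.14), RPL9 (2.26), AIF1 (2.29), MIX23 (2.37), CALM2 (2.40), RPL7 (2.41), CXCL8 (2.44), CHMP5 (2.44), LSM3 (2.49), UQCRHL (2.53), PSMA4 (2.54), HIGD1A (2.61), RPS3A (2.62), ANGPTL1 (2.72) and CSTA (2.74). From 2-fold to 4-fold were PKIG (1.01), GNMT (1.08), APOA2 (1.13), CREM (1.27), RPS20 (1.37), RPL27A (1.42), DYNLL1 (1.44), SAP18 (1.45), HP (1.62), KRT15 (1.89) and AADAC (1.91). Under 2-fold were HADHA (0.23), TPI1 (0.26), PGK1 (0.27), SHMT2 (0.30), SERPINA3 (0.35), FOXA3 (0.35), FDXR (0.37), BIRC5 (0.42), LDHA (0.53), ORM2 (0.58), MT-ND3 (0.63), ORM1 (0.65), HDAC3 (0.66), ID1 (0.69), APOA1 (0.82), DNTTIP1 (0.88), CCNE1 (0.89), AMBP (0.89), SLC25A20 (0.90), PMVK (0.98) and ECI1 (0.99).

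These values hold the GC and length trends of the libraries. With the trends removed, 48 of the 53 negative and 40 of the 47 positive differences passed the adjusted p in the same direction, and none passed in the opposite one. Of 42 negative and 26 positive differences called at over 2-fold, 18 and 19 were still called. Among those that were not, FASN was at -0.84, FLNA at -0.71, HDAC7 at -0.37, ACACB at -0.42 and AADAC at 0.77, each passing at under 2-fold, while SAP18 at 0.52, HDAC4 at -0.15, FUT1 at -0.87 and RXRA at 0.06 did not pass. The other 8 that did not pass were LSS, ENO1, HADHA, LDHA, ORM1, ORM2, PGK1 at -0.21 and MT-ND3 at -0.19, and RXRA, PGK1 and MT-ND3 thus changed sign.

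Of 50 drawn splits of genotype within each H89 condition, 1, the real one, gave as many genes as the 3491 with a differing H89 effect, and the highest of the others gave 3287. The real split and 7 others kept the real groups without H89, while the drawn splits that broke these groups called 0. Mixing groups that differ this much raises the spread within groups, so these 0 calls say little about chance. The 7 others called 2691 to 3287 genes, so the count follows the libraries without H89. For S434A vs WT without H89, H89 effect in WT and H89 effect in S434A, 1 of 10 splits of the 6 libraries, the real one, gave as many genes (3312, 5486 and 2540, with 0 as the highest other). For S434A vs WT with H89 all 10 of 10 gave 0. With 10 splits a share under 0.05 cannot be reached. Where the groups differ at many genes, mixed splits again raise the spread within groups.

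The replicates of S434A without H89 spread apart along GC content. Removal of each library's trend lowered the biological coefficient of variation of the group from 0.35 to 0.177, while the other groups were at most at 0.0464, which argues against a smooth bias on GC content and length as the whole of the spread, though it may account for part. A swap with another group would leave a partner out of place, and 0 of the 9 other libraries correlated best with a library of this group. RNA of treated or wild-type cultures mixed in would place genes between the neighbours, and 25% of 136 genes called against both lay outside their range, 24 above and 10 below, at the bound set for that test, so a mixture cannot be told apart. No biological explanation for a spread among replicates was tested.

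Along gene length the libraries without H89 separated from those with H89, with Spearman rho of -0.43 to -0.42 in WT without H89, -0.19 to -0.08 in S434A without H89 and 0.43 to 0.46 in the 6 libraries with H89. After the trends were removed 56.5% of the genes called for the H89 effect in WT were called in the same direction. This argues against a smooth bias on GC content and length as the whole of the effect, but not against other bias of preparation. GC content and length were taken per gene and not per transcript expressed, so some of such a bias can remain. Thinning every library to 17562754 counts left 5343 genes against 5486, which argues against depth. A library batch coinciding with WT without H89 cannot be told apart from that group, since the labels name no batch. The H89 effect in S434A, which uses no library of WT without H89, also went with gene length (Spearman rho 0.369), and an effect of H89 itself stays open.

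A genotype difference was present without H89 and not called with H89. Only 31.6% of its genes were called in the same direction after the trends were removed. Bias of library preparation cannot be told apart from the mutation for the rest. Nor can it for these genes, since the removal covers only smooth trends on GC content and length. The H89 effect differed between genotypes for 1889 genes after the trends were removed, 1208 of them among the 3491 found before and in the same direction (34.6%). This argues against a smooth bias on GC content and length as the whole of the difference, but not against other bias of preparation. A shift of WT without H89 alone cannot be told apart from the mutation, since H89 can act in S434A whether or not that group is shifted, and the 782 genes called for H89 effect in S434A after the trends were removed do not decide it. An effect of the mutation stays open and untested, confounded with any batch of the libraries without H89.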

How the results depend on the processing

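Removal of the GC and length trends, the same without S434A without H89 replicate 1, and the weight per group were chosen after seeing the data. For the comparison in which a gene was named, no value past both the fold and the adjusted p reversed its direction under an alternative. Among such values past the adjusted p at a smaller fold, 3 changed sign with the trends removed and did not pass there, namely CYP51A1 (0.86 to -0.03) and SQLE (0.36 to -0.51) for H89 effect in S434A and MT-ND3 (0.63 to -0.19) for the difference of H89 effects. HDAC1, CEBPB and FDXR, which did not pass, changed sign with the scaling in some comparisons. The threshold for a named gene is a 2-fold change with an adjusted p under 0.05. Of 179 named gene values, 170 stayed on their side of the threshold with RLE factors and with DESeq2, 175 with upper-quartile factors, 178 with limma-voom, with a weight per group and with at least 1 CPM, 169 without a filter, 131 with the trends removed (43 weaker, 5 stronger) and 132 without replicate 1 besides. With only the groups compared 143 of 154 did, 7 were weaker and 4 stronger, and on leaving out a library 1180 of 1224 values did, 29 were weaker and 15 stronger.

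With the trends removed the calls were 1640 (745 higher, 895 lower) for S434A vs WT without H89, 1983 higher for H89 effect in WT, 782 (348 higher) for H89 effect in S434A and 1889 (1021 higher, 868 lower) for the difference of H89 effects. Overlaps in direction were 598 for H89 in WT with H89 in S434A and 1360 for S434A with H89 in WT. Lists past the test were 1 for S434A vs WT without H89, 5 for S434A vs WT with H89 and 1 for the difference. Without replicate 1 of S434A without H89 besides, calls in the same order were 1641 (713 higher, 928 lower), 2051 higher, 573 (258 higher) and 1975 (1097 higher, 878 lower), and S434A vs WT with H89 gave 2, 1 higher (EVA1A-AS) and 1 lower (HYPK), chosen after their values were seen. DESeq2 and the weight per group each gave 1 gene there, 1 higher, the same EVA1A-AS. With only the groups compared, S434A vs WT without H89 had 921 lower and 2397 higher, and H89 effect in S434A had 832, 584 of them higher. No filter gave 1191 higher and 546 lower for H89 effect in S434A and an overlap of 968 between the H89 effects. The weight per group gave 192 lower for H89 effect in S434A. The cause was not tested.

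Leave-one-out gave 1582 (without S434A_minusH89 replicate 1) to 3504 (without S434A_minusH89 replicate 3) genes for H89 effect in S434A, 1148 to 3067 higher and 298 to 580 lower. Lists past the test ranged from 3 to 6 for S434A vs WT without H89 and from 0 to 6 for S434A vs WT with H89. RLE factors gave 3 lists for S434A vs WT without H89. With an estimated correlation 0, 0, 2, 0 and 0 lists passed in the 5 comparisons, in the order given in the methods.

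The share of calls that were higher moved with the scaling for H89 in WT, 58.3% with TMM, 48.7% with RLE, 51.4% with upper-quartile factors and 45.6% without a filter. The replicate number as a block gave 3345, 5454, 2679, 0 and 3488 genes and left 179 of 179 named values on their side. Whether replicate numbers pair the libraries was not settled. Of 18 same-number correlations 4 were over 0.1, with a range of -0.153 to 0.471 against -0.484 to 0.304 for other pairs. Yet 7 of the 12 libraries correlated best with a library of their own number. Thinning to the smallest library gave 3239, 5343, 2472, 0 and 3324 genes, so depth at that level limited few calls.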

Other observations

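The following lists of liver genes did not pass the camera test before removal of the GC and length trends. H89 in WT raised 9 and lowered 2 of 15 hepatocyte transcription factors (9 and 2 adjusted over the list alone, camera adjusted p = 0.134), with RXRA at 1.27, HNF4A at 1.11, FOXA1 at 0.94 and FOXA3 at -0.77. Over all genes 10065 of 14435 passed at any fold with H89 in WT. After the GC and length trends were removed this list passed at the preset correlation for H89 in WT, with 10 higher and 3 lower (camera adjusted p = 0.0378), and in S434A, with 8 higher and none lower (0.00558), and RXRA at 0.27 and HNF4A at 0.62 were under 2-fold and FOXA3 was at -0.45 in WT. H89 in S434A raised 11 and lowered 2 of 21 genes of cholesterol synthesis and uptake (11 and 2 adjusted over the list alone, camera adjusted p = 0.0515). The sterol synthesis genes LSS, CYP51A1 and SQLE were at 1.13, 0.86 and 0.36 and PMVK at -0.65. With the GC and length trends removed, CYP51A1 was at -0.03 and SQLE at -0.51, neither passing, and PMVK was at -0.26, while the list passed at the preset correlation (camera adjusted p = 0.00299). Of 14 genes of bile acid and xenobiotic metabolism 5 rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.854), with the cytochrome CYP1A1 at 1.53 and the transporter SLC51A at -0.77. The median of this list was -0.23 while its mean was 0.14 and the test pointed up.

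The remaining lists passed the test in none of the 5 comparisons by camera. The numbers higher and lower are given for S434A vs WT without H89, H89 effect in WT and H89 effect in S434A in that order. For 21 NRF2 and metallothionein genes they were 4 and 10, 8 and 12 and 5 and 9 (camera adjusted p = 0.311, 0.169 and 0.134). Inflammatory and NF-kB genes, 14 measured, gave 7 and 4, 7 and 4 and 2 and 4 (camera adjusted p = 0.695, 0.875 and 0.283). Hypoxia genes, 18 measured, gave 6 and 5, 6 and 4 and 6 and 3 (camera adjusted p = 0.986, 0.875 and 0.854). Genes of autophagy and the lysosome, 23 measured, gave 11 and 7, 12 and 7 and 2 and 7 (camera adjusted p = 0.439, 0.875 and 0.279). Replication-dependent histone genes, 9 measured, gave 1 and 4, 1 and 4 and 0 and 2 (camera adjusted p = 0.565, 0.408 and 0.411). Heat shock genes, 11 measured, gave 2 and 5, 2 and 4 and 3 and 2 (camera adjusted p = 0.389, 0.498 and 0.919). Of the fibroblast markers 1 was measured, with 1 and 0, 0 and 0 and 0 and 1 (camera adjusted p = 0.505, 0.904 and 0.252). Of the blood and endothelial markers 4 were measured, with 3 and 0, 1 and 0 and 0 and 2 (camera adjusted p = 0.311, 0.875 and 0.125).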
